A study of Homo sapiens with 18 samples.

How the data were processed

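The data are ChIP-seq read counts of Pol II phosphorylated on serine 5 in Rh30 cells with FKBP-tagged PAX3-FOXO1, from 2 libraries each of DMSO, 2 h of dTAG47 and 4 h of dTAG47. The authors deposited raw counts, whole numbers from 3 to 22091, for 12123 regions in 6 columns. The submitters' processing notes name Trimmomatic 0.32, Bowtie2, MACS2, DiffBind and DESeq2 and the genome builds hg19 and dm3, a fly build. Their roles, the way regions were called, merged and counted, and any removal of duplicates or subtraction of an input are not given in the sources used here. The regions are in human coordinates and are given as deposited, each with an end 400 above its start. Whether positions count from 0 or 1 is not given in the sources used here. The table holds no rows for fly reads and no totals of whole libraries, so a scaling by spike-in was not possible, and a change of all regions by the same factor would not be seen.

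The columns name the treatment and a letter, A or B, while the labels number the replicates 1 and 2. The columns were therefore tied to their groups and the letters were not tied to the numbers. The libraries of a group were first compared with a chi-square test of their counts. They differed by more than sampling noise, with a chi-square per degree of freedom of 2.33 for DMSO, 1.50 for 2 h and 2.26 for 4 h, and each was counted as 1 replicate.

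Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors and all 6 libraries in 1 fit, so that the 3 groups share an estimate of the spread. The filter filterByExpr removed 0 regions. P-values were adjusted by Benjamini-Hochberg over the 12123 regions and called under 0.05. The common dispersion was 0.00648, a biological coefficient of variation of 8.05%, and the prior had 43.6 degrees of freedom. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, with a median of 0.169 at 2 h. Normalized values are TMM-scaled CPM, given as mean ± SD.

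The test was tried on simulated counts for the 12123 regions with known changes. For the 2 h comparison it recovered 54% of 1.5-fold and 88% of 2-fold changes, with 10 false calls, and for the 4 h comparison 36% and 90%, with 6 false calls. In 50 simulations with no change, the median number of calls was 0 and the highest 1 in either comparison. Both kinds of simulation drew counts from the fitted model, which the test assumes. They therefore do not show how many calls on the measured counts are false. Simulated changes of 1.5-fold were often missed.

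The groups, tests, alternatives and the rule for the regions to name were chosen before the data were examined. For each time against DMSO, the rule took called regions with a mean of at least 20 counts and with both treated libraries on the same side of both DMSO libraries, and named the 10 largest falls and the 10 largest rises. For 4 h against 2 h it took the 5 lowest p-values in each direction. Regions are named by chromosome and position in hg19. An annotation of that build was not used here, and coordinates of another build were not converted, so regions were tied to no gene and to no promoter, exon or intron. For that reason the tests of gene lists, of promoters against gene bodies, and of PAX3 and FOXO1 themselves, all planned, were not run.

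The placement of called regions was tested in Python 3.11.15 with scipy 1.17.1. Fisher's exact tests compared each chromosome with the others, with Benjamini-Hochberg adjustment over the chromosomes of a direction and time. The number of called regions with another of the same direction within 100 kb was compared with 100000 random sets of as many regions. Stretches were formed by joining called regions of the same direction no more than 200 kb apart, a distance raised from 100 kb after a first look. The placement tests were chosen after the calls had been seen. Also set beforehand were other scalings (median of ratios, total count, cyclic loess with limma-trend), other tests (DESeq2 1.42.0, and limma-voom in limma 3.58.1), other filters, fits, dispersions and thresholds, and leaving out each library. A block by column letter, a covariate for the share of counts in the 3 highest regions, and distances of 50 kb for close regions and 100 kb for stretches were added after the data had been seen. The 3 highest regions start at 121484944 on chromosome 1, 61968821 on chromosome 7 and 58779007 on chromosome 6. They were taken to stand for background, which was not tested.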

Results

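RNA polymerase II (Pol II) phosphorylated on serine 5 of its C-terminal domain, the form found mostly near transcription start sites, was measured by ChIP-seq in Rh30 cells. Rh30 is an alveolar rhabdomyosarcoma line that depends on the fusion transcription factor PAX3-FOXO1. In the cells used here the fusion protein carries an FKBP tag, which lets the small molecule dTAG47 direct it to degradation. Cells received DMSO, the solvent, or 500 nM dTAG47 for 2 h or 4 h, with 2 libraries per group and 6 in all. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The series has 18 samples, of which the 12 made with another antibody were not analysed here.

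Counts were given for 12123 regions of the hg19 genome, each spanning 400 bases between its start and end, on 24 chromosomes. Total counts were 1792013 and 1430934 in DMSO libraries A and B, 1445058 and 1343568 in the 2 h libraries A and B, and 1585579 and 962251 in the 4 h libraries A and B. The median region had 120 counts in DMSO library A and 60 in 4 h library B, the deepest and the shallowest library. Across regions, log2 CPM (counts scaled to a common library total) of the libraries of a group correlated with Pearson's r of 0.952 for DMSO, 0.96 for 2 h and 0.946 for 4 h. Regions are not independent replicates, and these values describe the libraries only. The 3 regions with the highest counts took 1.77% and 2.61% of the counts in DMSO libraries A and B, 2.61% and 3.21% at 2 h, and 2.61% and 4.17% at 4 h.

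The first comparison asked where Ser5 Pol II changed within 2 h of dTAG47. It fell at 48 regions and rose at 269, together 2.61% of the 12123 regions (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was -0.63 among the regions that fell and 0.67 among those that rose, and 4 regions fell and 36 rose at least 2-fold. In 317 of the 317 called regions both 2 h libraries lay on the same side of both DMSO libraries in normalized counts. That arrangement held for 43.7% of all regions, and chance alone gives 33.3%. Without adjustment, 659 regions were lower and 1076 higher at p under 0.05.

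The region with the largest rise at 2 h lay on chromosome 15 at 65588533 to 65588933, where the signal went from 124 ± 3.21 CPM in DMSO to 453 ± 31.0 CPM at 2 h (SD, n = 2 each), a 3.65-fold increase (log2 fold change 1.87, SE 0.15, edgeR adjusted p = 7.89e-12). A second region on the same chromosome, at 65597070 to 65597470, rose by 1.5 on the log2 scale (SE 0.15, adjusted p = 1.78e-09). A similar pair stood on chromosome 1, where the region at 45196343 to 45196743 rose by 1.55 and the region at 45187147 to 45187547 by 1.40. On chromosome 17, the region at 56756707 to 56757107 rose by 1.54, the region at 56708875 to 56709275 by 1.46 and the region at 8076517 to 8076917 by 1.43. The remaining regions among the 10 largest rises lay on chromosome 1 at 210547086 to 210547486 (1.57), 78469753 to 78470153 (1.5) and 28975143 to 28975543 (1.46). The last of these had the highest signal of the 10, with 309 ± 40.0 CPM in DMSO and 847 ± 26.4 CPM at 2 h.

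The largest fall at 2 h was on chromosome 16 at 1487379 to 1487779, from 193 ± 22.4 CPM to 72.7 ± 2.84 CPM (log2 fold change -1.41, SE 0.15, edgeR adjusted p = 2.61e-09). It was followed by regions on chromosome 1 at 209719978 to 209720378 (-1.41, SE 0.30, adjusted p = 0.00269) and on chromosome 17 at 6458833 to 6459233 (-1.22, SE 0.20, adjusted p = 7.86e-05). Both of the next regions lay on chromosome 9, at 133558924 to 133559324 (-1.06) and at 133536057 to 133536457 (-0.87). Smaller falls at low-count regions completed the 10, on chromosome 2 at 222437937 (-0.86), chromosome 14 at 23907504 (-0.84), chromosome 10 at 30024409 (-0.82), chromosome 9 at 22447082 (-0.80) and chromosome 16 at 79633788 (-0.78). Their adjusted p-values were 0.0120, 0.0214, 0.0158, 0.0336 and 0.0102 in that order. None of these 5 passed the threshold without DMSO library B, where the log2 fold changes were -0.71, -0.71, -0.70, -0.65 and -0.59 (adjusted p = 0.117, 0.126, 0.112, 0.205 and 0.145), or without 2 h library B, where they were -0.90, -0.62, -0.93, -0.65 and -0.71 (adjusted p = 0.0640, 0.301, 0.0524, 0.299 and 0.114). Those at 23907504 and 22447082 also missed it with cyclic loess scaling and limma-trend as the test (-0.78 and -0.71, adjusted p = 0.0643 and 0.0978). Without 2 h library A it was missed on chromosome 2 (-0.81, adjusted p = 0.128), chromosome 10 (-0.71, 0.222) and chromosome 9 (-0.97, 0.0713), and at 209719978 on chromosome 1 (-1.21, 0.0749). Leaving out a library kept the sign of each of these fold changes.

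Rises made up 84.9% of the 2 h calls with TMM scaling and 65.6% with total count scaling, under which 87 regions fell and 166 rose. Cyclic loess with limma-trend gave 26 falls and 130 rises, DESeq2 3 and 96, and a fit of only the 2 groups compared 81 and 366. The covariate for the share of counts in the 3 highest regions gave 157 and 382, of which 70.9% were rises. A block by column letter, added after the data had been seen, gave 230 and 629, of which 73.2% were rises. The counts also rested on single libraries. Fewer falls and rises were called without either 2 h library, and fewer rises without DMSO library A. More were called without either 4 h library, although these enter this comparison only through the estimate of spread and the scaling.

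**Figure D1:**
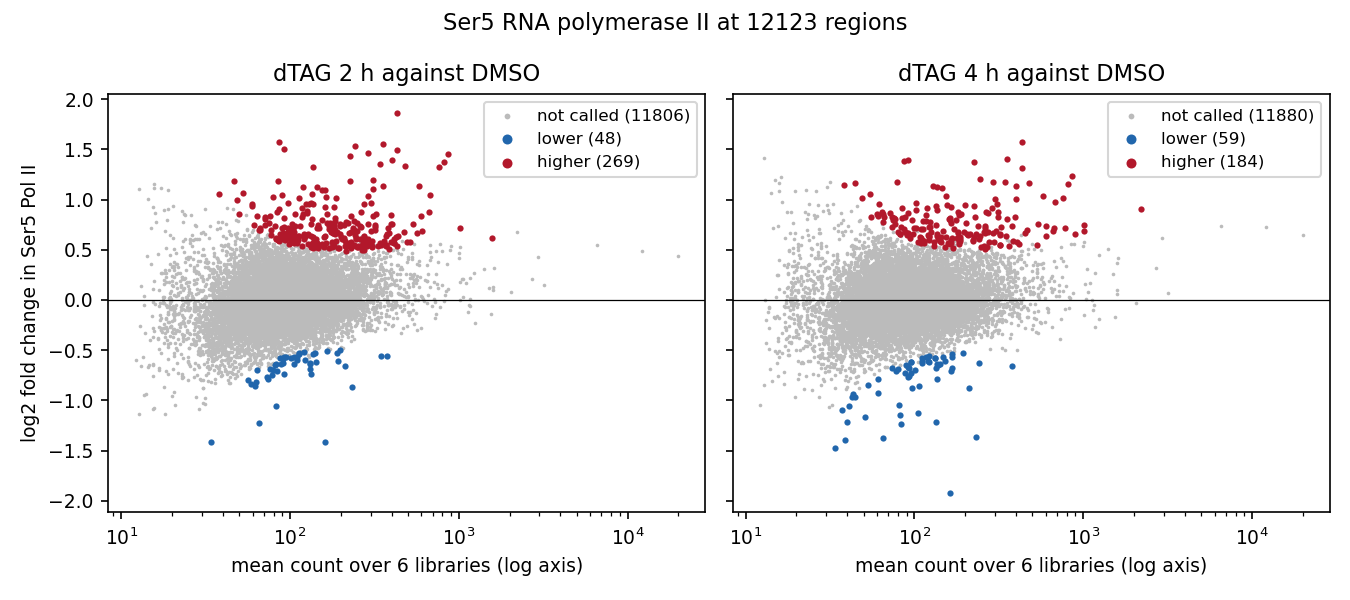
Each point is 1 of the 12123 regions, with its mean count over the 6 libraries on a log axis and its log2 fold change in Ser5 Pol II at 2 h (left) or 4 h (right) against DMSO. Called regions are coloured, 48 lower and 269 higher at 2 h and 59 lower and 184 higher at 4 h, and uncalled regions are grey.

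The second comparison asked where Ser5 Pol II differed from DMSO after 4 h. It fell at 59 regions and rose at 184, together 2.0% of those tested, with a median log2 fold change of -0.70 among the falls and 0.72 among the rises (edgeR, adjusted p under 0.05). At least 2-fold changes were found at 14 of the regions that fell and 26 of those that rose. In 237 of the 243 called regions both 4 h libraries lay on the same side of both DMSO libraries, against 40.8% of all regions and 33.3% by chance. Without adjustment, 617 regions were lower and 994 higher at p under 0.05.

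The chromosome 16 region at 1487379 to 1487779 again had the largest fall, to 51.6 ± 5.31 CPM (SD, n = 2), 3.80-fold below DMSO (log2 fold change -1.93, SE 0.16, edgeR adjusted p = 6.45e-12). The regions at 209719978 on chromosome 1 (-1.47, SE 0.31, adjusted p = 0.00349) and 6458833 on chromosome 17 (-1.37, SE 0.21, adjusted p = 2.77e-05) fell at this time too. Of the 10 largest falls, 3 lay within a short stretch of chromosome 9, at 133536057 (-1.36), 133558924 (-1.24) and 133355675 (-1.21). The others were on chromosome 7 at 138666190 to 138666590 (-1.39), chromosome 15 at 59730363 to 59730763 (-1.22), chromosome 12 at 30263575 to 30263975 (-1.16) and chromosome 19 at 49175545 to 49175945 (-1.14). None of these last 4 was called at 2 h. With 1 library left out, some missed the threshold with the sign of the fold change kept. These were the chromosome 1 region without 4 h library A (-1.18, adjusted p = 0.100), the chromosome 7 region without 4 h library B (-1.14, 0.0824), the chromosome 15 region without DMSO library B (-1.05, 0.0824) or 4 h library B (-0.99, 0.154), and the chromosome 12 region without DMSO library B (-0.83, 0.135).

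The largest rise at 4 h was again at 65588533 on chromosome 15, with 370 ± 0.620 CPM (SD, n = 2), 2.98-fold above DMSO (log2 fold change 1.58, SE 0.16, edgeR adjusted p = 1.69e-09). Its neighbour at 65597070 rose by 1.31. On chromosome 1 the regions at 45196343, 78469753, 210547086 and 28975143 rose by 1.41, 1.39, 1.38 and 1.24, and on chromosome 17 those at 8076517 and 56756707 rose by 1.38 and 1.21. The 10 largest rises were completed by regions on chromosome 2 at 122288541 to 122288941 (1.17, SE 0.15, adjusted p = 1.01e-06) and on chromosome 4 at 190842379 to 190842779 (1.18, SE 0.23, adjusted p = 0.00134). The chromosome 4 call ended without 4 h library B (0.73, adjusted p = 0.127), with a robust dispersion (adjusted p = 0.232) and with the share of counts in the 3 highest regions as a covariate (0.36, adjusted p = 0.532).

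Rises made up 75.7% of the 4 h calls with TMM scaling and 59.1% with total count scaling, under which 83 regions fell and 120 rose. DESeq2 called 5 falls and 53 rises. The covariate for the share of counts in the 3 highest regions gave 146 falls and 231 rises, so that 61.3% of calls were rises. It kept 97 of the 184 rises. A block by column letter gave 203 falls and 540 rises. Leaving out 1 library moved the counts to 27 falls and 93 rises without 4 h library B, to 89 rises without DMSO library A and to 314 rises without DMSO library B.

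**Figure D2:**
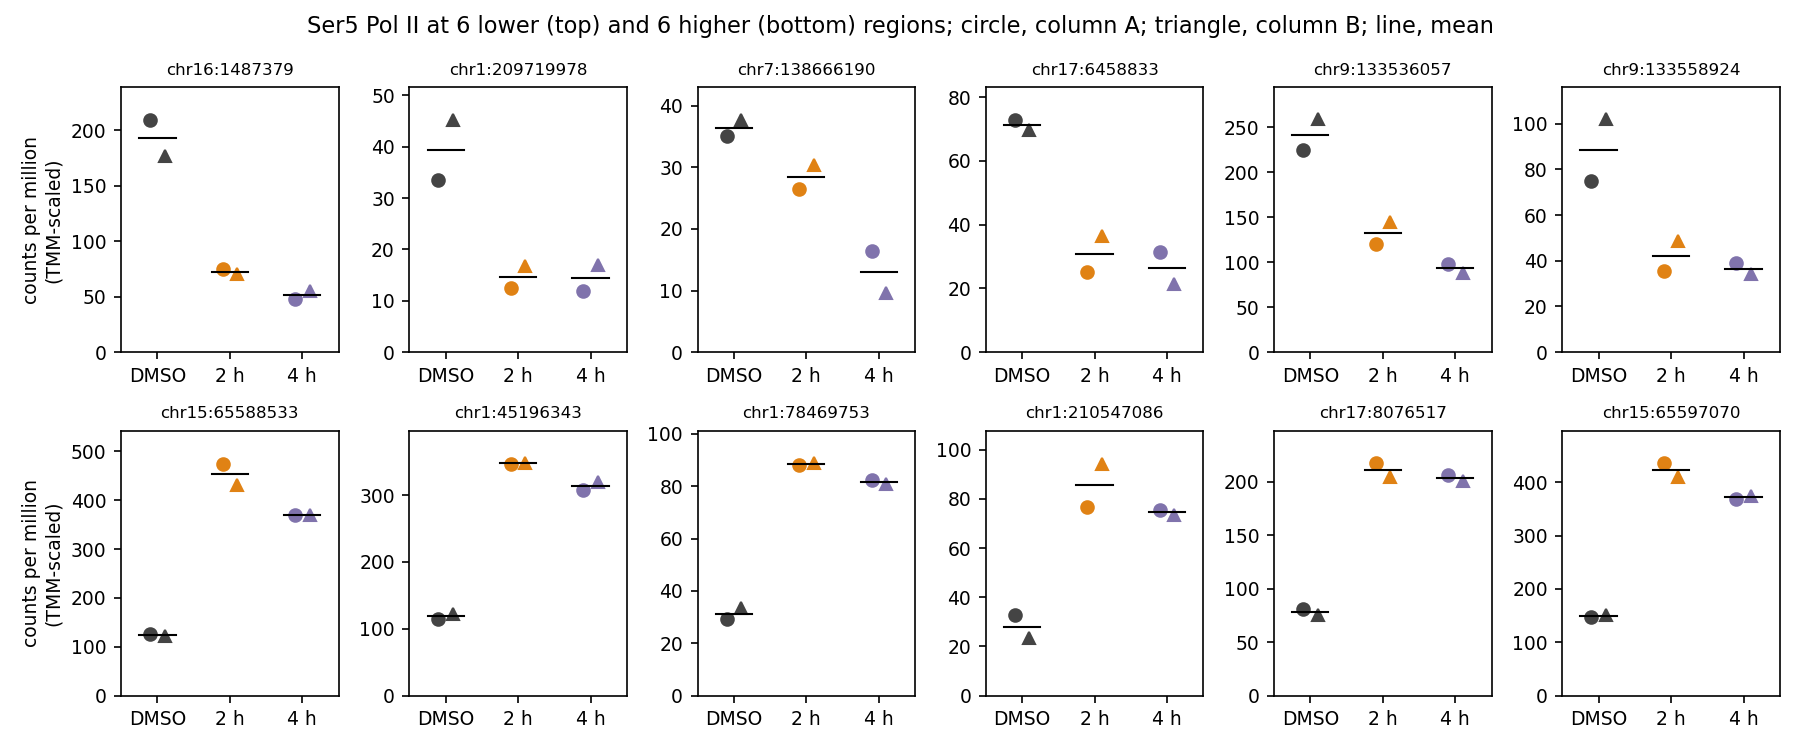
Ser5 Pol II in TMM-scaled CPM in each library, for the 6 regions with the largest fall at 4 h (top) and the 6 with the largest rise (bottom). Circles are column A, triangles column B and lines the means of the 2 libraries; at the region on chromosome 16 at 1487379 the mean went from 193 in DMSO to 72.7 at 2 h and 51.6 at 4 h.

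Between the times, 19 regions fell at both 2 h and 4 h and 128 rose at both, and 0 were called in opposite directions. Of the 10 largest falls, 5 were the same regions at both times, and of the 10 largest rises, 8. Independent lists of these sizes would share 0.234 falls and 4.08 rises. In 50 simulations of unchanged groups, both set against the same simulated DMSO libraries, at most 1 region was called in a comparison. That is too few to give a shared count to compare with. Across regions, which are not independent replicates, the log2 fold changes at 2 h and 4 h had a Pearson's r of 0.749, against a mean of 0.457 in the simulations. Their covariance was 0.0541 against a simulated 0.0176, a difference of 0.0365, and 75.4% of regions had the same sign against 65.2% simulated. The simulated counts were drawn separately for each region, so differences shared by many regions of a library are absent from them. The simulated values may therefore be too low. The 2 DMSO libraries were not divided between the 2 times, so part of the excess may come from the shared controls. The shared counts were 3 falls and 48 rises with DESeq2, 69 and 199 with the covariate, and 82 rises with cyclic loess and limma-trend. With a block by column letter they were 69 and 362. They also moved with single libraries, to 7 falls without 2 h library A, 7 falls and 84 rises without 2 h library B, 10 falls without 4 h library B, and 72 and 220 rises without DMSO libraries A and B.

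The third comparison set 4 h against 2 h directly. In edgeR 0 regions passed the threshold, with a lowest adjusted p of 0.998, and 251 regions were lower and 145 higher at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0, with 33 and 385 regions at an unadjusted p under 0.05. In each of these 3 fits that is a smaller share of the 12123 regions than the 0.05 that chance gives. With a block by column letter, edgeR put 734 regions under it and called 0 (lowest adjusted p = 0.436). The absence of calls does not show that the 2 times are equal. The lowest unadjusted p-values for a lower signal at 4 h belonged to regions on chromosome 19 at 40030451 to 40030851 (log2 fold change -0.60, SE 0.16), chromosome 5 at 137801033 to 137801433 (-0.65, SE 0.18), chromosome 19 at 49175545 to 49175945 (-0.75, SE 0.21), chromosome 6 at 132272248 to 132272648 (-0.51, SE 0.15) and chromosome 7 at 2913761 to 2914161 (-0.51, SE 0.15). For a higher signal they belonged to regions on chromosome 21 at 17154366 to 17154766 (0.75, SE 0.23), chromosome 6 at 117596388 to 117596788 (0.66, SE 0.21), chromosome 19 at 40023201 to 40023601 (0.49, SE 0.16), chromosome 2 at 198318170 to 198318570 (0.59, SE 0.20) and chromosome 6 at 143771520 to 143771920 (0.47, SE 0.17). All 10 had an adjusted p of 0.998. The differences between the lists at 2 h and 4 h above, such as the 4 falls named at 4 h and not called at 2 h, were therefore not past the threshold in the direct test. Without 4 h library A, the region on chromosome 16 at 33974180 to 33974580 was higher at 4 h (log2 fold change 1.05). That value rests on 4 h library B alone, with 147 CPM. The region had 65.5 CPM in 4 h library A and 58.0 and 85.1 in the 2 h libraries A and B. With the share of counts in the 3 highest regions as a covariate, added after the data had been seen, 4 regions were lower at 4 h, on chromosome 1 at 11968404 (-0.30), chromosome 12 at 57630049 (-0.31), chromosome 21 at 9825380 (-0.39) and chromosome 5 at 177542965 (-0.52), with adjusted p-values from 0.00686 to 0.0468.

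The regions that changed were unevenly placed in the genome. On chromosome 9, 4 of the 5 regions measured between 133355675 and 133559324 fell at both times, with a median log2 fold change of -0.80 at 2 h and -1.22 at 4 h. The fifth, at 133454593 to 133454993 in the middle, had log2 fold changes of -0.02 and -0.15 and was not called. On chromosome 6, 11 of the 17 regions between 26021344 and 26285756 rose at one time or the other, as did 7 of the 7 regions between 27792209 and 27861060. With the share of counts in the 3 highest regions as a covariate, 3 of the 4 falls on chromosome 9 stayed called at 2 h and 4 of 4 at 4 h. In the 2 stretches of chromosome 6, 8 of 8 and 4 of 6 rises stayed called at 2 h, and 6 of 9 and 3 of 6 at 4 h. These stretches were chosen after the fold changes had been seen, and the 200 kb joining distance after 100 kb had been tried, at which the chromosome 9 falls form 2 pairs. By chromosome, 36 of the 637 regions on chromosome 6 rose at 2 h, or 5.65% against 2.22% of all regions (Fisher's exact test, adjusted p = 5.03e-06), and 32 of them rose at 4 h, or 5.02% against 1.52% (exact test, adjusted p = 4.28e-08). On chromosome 9, 8 of the 560 regions fell at 2 h, or 1.43% against 0.396% (exact test, adjusted p = 0.0348), and 6 fell at 4 h, or 1.07% against 0.487% (adjusted p = 1). Of these 8 and 6 falls, 4 and 4 lie in the stretch above, and the exact tests count neighbouring regions as independent. On chromosome 6, the 2 stretches above hold 8 and 6 of the 36 rises at 2 h and 9 and 6 of the 32 at 4 h. The exact tests are therefore not separate from these stretches. Of 96 two-sided tests, by chromosome, direction and time, only the 2 on chromosome 6 and that of the 2 h falls on chromosome 9 had an adjusted p under 0.05.

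**Figure D3:**
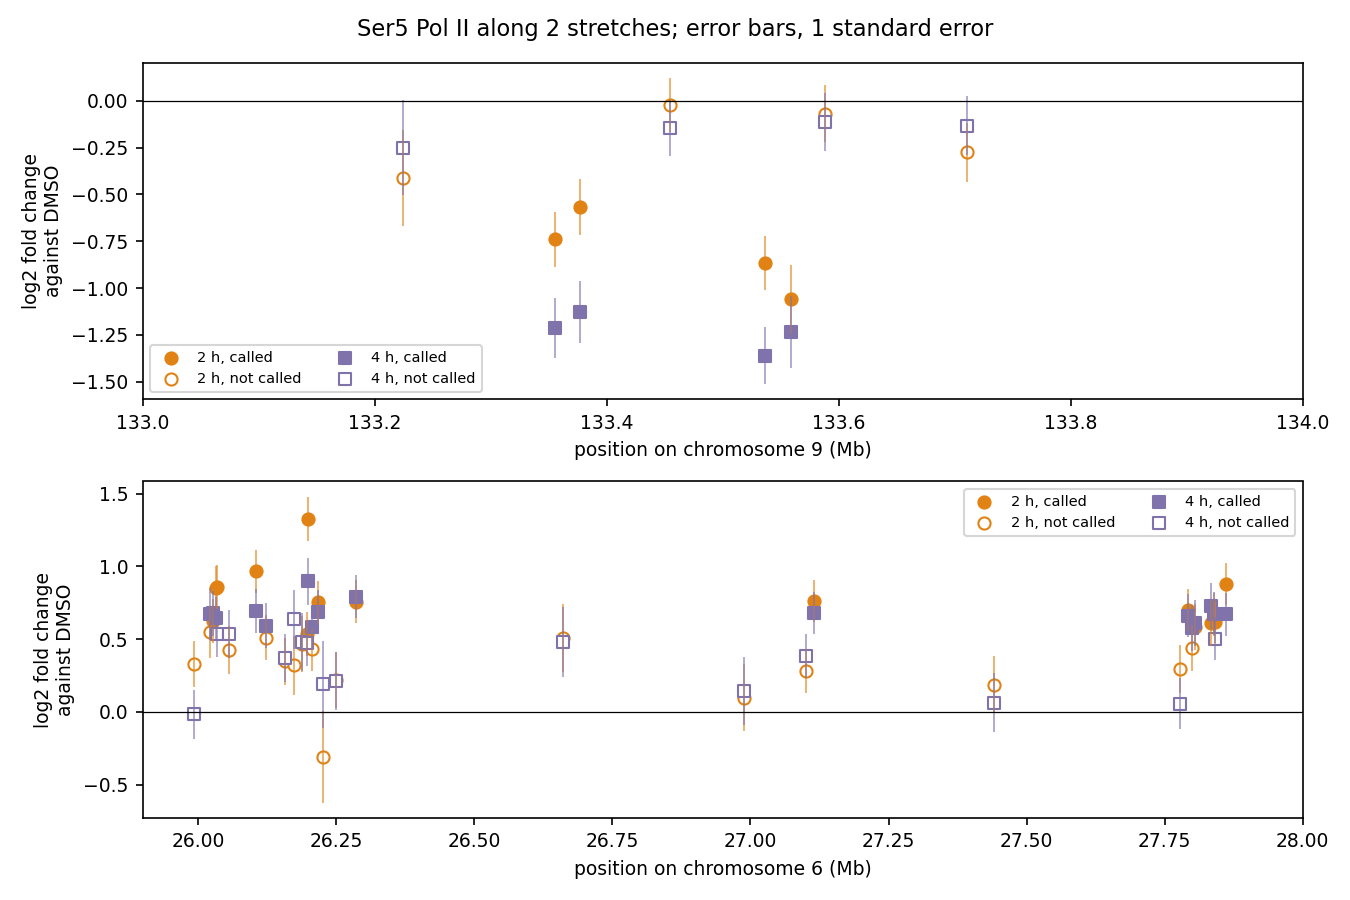
Log2 fold change of Ser5 Pol II against DMSO at 2 h (circles) and 4 h (squares) along a stretch of chromosome 9 (top) and of chromosome 6 (bottom), with position in megabases on the horizontal axis, error bars of 1 standard error, and filled symbols for called regions. On chromosome 9, 4 called regions lie below 0 at 4 h and the region between them near -0.15; on chromosome 6, 15 of the 31 regions shown were called higher at 2 h and 16 at 4 h.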

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

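The block by column letter, the covariate for the share of the 3 highest regions and the tests with it were chosen after the data had been seen. No named region changed direction under any alternative that was run. For the regions named at 2 h, 339 alternative values kept their side of the threshold and 30 lost the call, and at 4 h 352 kept it and 16 lost it. DESeq2 gave no adjusted p for 10 of the 20 regions named at 2 h and 9 of the 20 at 4 h, and these are not counted as lost. Among the named rises, only that on chromosome 4 at 4 h lost its call under an alternative that gave an adjusted p. Of simulated 1.5-fold changes, 54% were recovered at 2 h and 36% at 4 h. How much of this is due to depth and how much to the number and spread of the libraries was not tested. A filter for low counts removed 0 regions, so its omission tested nothing.

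The counts of calls moved more. With total count scaling there were 87 falls and 166 rises at 2 h and 120 rises at 4 h. Cyclic loess, tested with limma-trend in place of edgeR, gave 26 falls and 130 rises at 2 h, and 82 rises shared between the times. DESeq2 called 3 falls and 96 rises at 2 h, 5 and 53 at 4 h, and 3 and 48 shared, with no adjusted p for 7756 and 6346 regions. With only the 2 groups compared in the fit, 81 regions fell and 366 rose at 2 h. A tested fold change of at least 1.5 left 1 fall and 21 rises at 2 h, 4 and 11 at 4 h, and 1 and 11 shared. An adjusted p under 0.01 left 10 and 133, 18 and 83, and 8 and 66. The last 2 are stricter by construction; for the other settings the cause was not tested. Median of ratios scaling, limma-voom, a mean of at least 50 counts and a robust dispersion kept every one of these counts within 1.5 times.

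Leaving out each of the 6 libraries gave 15 to 87 falls and 127 to 365 rises at 2 h, 27 to 71 falls and 89 to 314 rises at 4 h, 0 to 1 regions for 4 h against 2 h, and 7 to 26 shared falls and 72 to 220 shared rises. The group left with 1 library is assumed to vary like the others.

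With a replicate block by column letter there were 230 falls and 629 rises at 2 h, 203 and 540 at 4 h, and 69 and 362 shared, and all 48 falls and 269 rises at 2 h and all 59 and 184 at 4 h stayed called. The differences between columns A and B correlated across regions with an r of 0.219 for DMSO and 2 h, 0.279 for DMSO and 4 h and 0.158 for 2 h and 4 h. This is a hint from the data that columns of a letter share something. In each group column B had a higher share of counts in the 3 highest regions and a lower total count than column A. The block and the covariate are therefore not separate checks. The labels give no pairing by letter, and the planned block by replicate number was not run because the columns carry no number.

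With the covariate there were 157 falls and 382 rises at 2 h, 146 and 231 at 4 h, and 69 falls and 199 rises shared. Of the 269 rises at 2 h, 67 lost the call, and at 4 h 97 of 184 stayed called. For 4 h against 2 h, 4 regions were lower with the covariate, on chromosome 1 at 11968404, chromosome 12 at 57630049, chromosome 21 at 9825380 and chromosome 5 at 177542965, with adjusted p-values of 0.0468, 0.00686, 0.0303 and 0.0468. The planned scaling by spike-in, the gene list tests with their alternatives, and the wider promoter window were not run.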

Other observations

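All tests in this part were chosen after the result they bear on, or part of it, had been seen. For the test of the 18 regions around the chromosome 9 stretch, the calls in the stretch had been seen. Only its bound was written before its value.

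Regions that changed in the same direction lay close together more often than random regions. Of the 88 regions that fell at 2 h or 4 h, 12 had another within 100 kb, against a mean of 1.58 in 100000 random sets of 88 regions (permutation p = 1.1e-04). Of the 325 that rose, 92 had one, against 20.6 (permutation p = 1e-05, the smallest the random sets can give). Within 50 kb the numbers were 10 (permutation p = 9e-05) and 74 (permutation p = 1e-05). Chance placement that treats all measured regions alike is thus argued against in both directions. The random sets were not matched for counts. The mean count of called rises had a median of 176.7 at 2 h and 166.2 at 4 h, against 92 over all regions. For called falls the medians lay closer to 92. Whether called regions lie closer together than other regions with similar counts was not tested. Random sets also do not keep the local similarity that neighbouring regions can have for technical reasons.

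For the falls, the stretch with the most called regions was that of chromosome 9, from 133355675 to 133559324, when regions up to 200 kb apart were joined; at 100 kb it is 2 pairs. A change of like size in most regions within 1 Mb outside it is argued against. The 18 regions there had a median log2 fold change of -0.10 at 4 h (from -0.59 to 0.24), against -1.22 for the 4 called regions. The 15 of them more than 200 kb away, which the joining left free to be called, had a median of -0.02. A smaller change beyond the stretch, or one in single regions, stays open. An even change from the first to the last of the 4 is also argued against, since the region between the pairs had -0.15 (SE 0.15). With the covariate for the share of the 3 highest regions, 3 of the 4 stayed called at 2 h and 4 of the 4 at 4 h. No biological explanation of this stretch was tested, and which gene or genes it holds was not examined.

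For the rises, the covariate takes the 3 highest regions to stand for background, which was not tested. It cannot decide whether a lower enrichment over background is the whole cause of the closeness of the rises. Its slope is set only by differences between the 2 libraries of a group and may carry another difference between the letters. Of the 214 rises that stayed called with it, 58 had another within 100 kb, against 9.12 in random sets (permutation p = 1e-05, the smallest they can give). Of the 11 stretches of rises, 5 kept every call with the covariate, 4 kept some and 2 kept none. Those that kept every call were on chromosome 1 from 28832384, chromosome 6 from 30566441, chromosome 17 from 41393142 and from 56708875, and chromosome 20 from 60942049. On chromosome 6, 8 of 8 rises at 2 h and 6 of 9 at 4 h stayed called from 26021344 to 26285756, and 4 of 6 and 3 of 6 from 27792209 to 27861060. On chromosome 17 the numbers were 2 of 3 and 1 of 3 from 7387566 to 7790298, and on chromosome 11 they were 1 of 3 and 1 of 2 from 65212950 to 65275224. No call was kept on chromosome 10 from 42387104 to 42529790 (0 of 1 at 2 h and 0 of 5 at 4 h) or on chromosome 2 from 92296652 to 92318886 (0 of 3 at 4 h, with none to keep at 2 h). In each called region of these 2 stretches, library B had the higher CPM in every group, as it had the higher share of counts in the 3 highest regions. At 42399181 on chromosome 10, 4 h library A had 444 CPM and DMSO library B 469. At 92307342 on chromosome 2 they had 141 and 146. Both stretches may therefore move with the 3 highest regions.

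More regions rose than fell at 2 h, 269 against 48. Library scaling stays open as a cause: of 3 other scalings, only total count moved the median log2 fold change of all regions by more than 0.05, by -0.06, and it brought the rises to 65.6% of the calls, while a scaling by spike-in was not run. A lower enrichment over background in the treated libraries also stays open. The values below take the 3 highest regions to stand for background, which was not tested. With the covariate 382 regions rose and 157 fell. Rises were then 70.9% of the calls (95% Wilson interval 66.9% to 74.5%, counting regions as independent). The covariate cannot decide this, since its slope is set only by differences between the 2 libraries of a group. In each group library B had the higher share of counts in the 3 highest regions and the lower total count. Another difference between the letters could thus enter the slope. The falls grew more than the rises, and the 70.9% does not show which rises stayed. The 4 h libraries entered the 2 h comparison only through the estimate of spread and the scaling. In them, the log2 ratio of library B over A was 0.0017 above that of uncalled regions in the regions called higher at 2 h (95% bootstrap interval -0.04 to 0.03). It was -0.10 from it in those called lower, against 0.71 in the 3 highest regions. A large spread there can hide a call, and in a fit without these libraries the differences were 0.03 (-0.01 to 0.06) and -0.09 (-0.13 to -0.04), with 9.29% of the 366 rises and 0% of the 81 falls above the 95th percentile of uncalled regions. By this ratio the rises were not mostly like the 3 highest regions. Calling favours regions with small differences between A and B in DMSO and 2 h. Those differences correlated with the 4 h ones (r of 0.279 and 0.158), so the ratio may be drawn towards that of uncalled regions. A part of background in rises and falls stays open. For single rises it stays open: 75.1% kept the call at 2 h (95% Wilson interval 69.6% to 79.9%, around the bound of 75% that was set), and at 4 h 52.7% kept it (45.5% to 59.8%, below the bound), so that part of the 4 h rises may follow background; in the 67 and 87 that lost the call, the median log2 fold change went from 0.62 to 0.46 and from 0.70 to 0.41, and the median SE from 0.16 to 0.18 and from 0.18 to 0.20. An effect of losing the fusion protein, the difference the design names, was not tested apart from these.

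The highest count was at 121484944 on chromosome 1, with a mean of 19941 counts, 217 times the median region. Between 57475475 and 58316317 on chromosome 12, 81 regions had a median of 428 counts against 92 over all regions, with 1 region called higher at 2 h and 0 called at 4 h. Of these, 98.8% lay above the median region in every library, against 37.5% of all regions. No input library or DNA copy number was used here, so whether the high counts reflect Ser5 Pol II was not tested. These stretches and regions were picked for their counts.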
